A study of Mus musculus with 12 samples.

How the data were processed

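The samples were ventricular tissue from male C57BL/6 mice aged 13, 15 or 18 weeks. Right ventricles (RV) came from sham mice at 3 weeks and from mice 1, 3 or 6 weeks after a clip was placed on the pulmonary artery (PAC). Left ventricles (LV) came from sham mice and from mice with a constricted aorta (TAC), each at 3 weeks. Each of the 6 groups held 2 Affymetrix whole-transcript arrays, so n = 2 arrays per group throughout. The labels do not say whether each array held tissue from a separate animal, or whether sham RV and sham LV pieces came from the same hearts.

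The values analysed were the log2 expression values deposited by the authors. According to the submitters' processing notes they were made with RMA in Affymetrix Power Tools. The version of that software, the library files and the genome build are not given in the sources used here. The deposited values ran from 1.71 to 14.78, with array medians between 6.32 and 6.4, and were used without further scaling. Of 35556 probe sets, 23410 were listed in the annotation, 21789 with a single gene and 1621 with several genes, which left 12146 unlisted. Of the probe sets with a single gene, 91 carried a gene missing from the reference table of gene names and were kept under their given name. Where a gene had several probe sets, which held for 999 genes, the probe set with the highest mean over the 12 arrays was kept. This gave 19938 genes. Probe sets that were unlisted or carried several genes were tested apart and were not named.

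A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 6 residual and 4.6 prior degrees of freedom. There were 9 comparisons. PAC at 1, 3 and 6 weeks and the mean of the 3 times were each compared with sham RV. PAC at 6 weeks was compared with PAC at 1 week, TAC with sham LV, sham RV with sham LV, and PAC with TAC at 3 weeks. The last was the interaction of chamber and obstruction at 3 weeks, that is the PAC change less the TAC change. Moderated p-values were adjusted by the Benjamini-Hochberg method over the 19938 genes, and a gene passed at an adjusted p of 0.05. Changes are log2 differences with the standard error from limma, and levels are means with the standard deviation over 2 arrays. The median standard error was 0.112 for a pair of groups, 0.092 for the mean of the 3 times and 0.159 for the interaction. An exact permutation test of 2 against 2 arrays cannot give a p below 0.33, so all gene p-values rest on the moderated model.

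A total of 31 gene lists with 844 genes were fixed before the data were examined, and 790 of the genes were measured. The lists covered cardiomyocyte load and metabolism, matrix and signalling pathways, cell cycle, cell types of the heart, tissues that may be dissected along with it, and stress or clock responses. Lists with at least 5 measured genes were tested, which left 30 lists, because the erythroid list had 4 measured genes. Each list was tested with limma camera at a preset correlation of 0.01, adjusted over the 30 lists within a comparison. The same test was run with a correlation estimated from the data, and fry was the other list tool. Members were also counted with p-values adjusted over the list alone.

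Genes are named by a rule. For each comparison up to 10 of the largest increases and up to 10 of the largest decreases are named among genes that passed and whose arrays did not overlap between the sides. Where fewer than 5 genes passed, the 5 with the smallest p are named as not passing. Up to 4 members are named per list, with those that passed first. Nppa, Nppb, Myh6, Myh7, Acta1, Hand1, Hand2 and Tbx5 are given in every comparison. Predicted gene models, olfactory and vomeronasal receptors and small RNA genes are counted but not named.

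The alternatives fixed before the values were opened were cyclic loess scaling of the deposited values, the mean over probe sets of a gene, and leaving out genes below the median level of 6.74. The others were a trended and robust variance prior, a fit to only the arrays compared, a block for replicate number, and leaving out each array in turn. Leaving out PAC 1 week array 2 together with sham LV array 2 was added after the data were seen, because the former belongs to the pair with the lowest correlation between mates (0.992), of which it lies farther out on the first principal component (30.9 against 4.4), and the latter higher atrial markers than its mate (8.53 against 7.12 over 4 markers). PAC 3 week array 2 exceeded its mate in these markers by more (9.3 against 7.66) and was kept. When a group is left with 1 array, its comparison borrows the spread of the other groups.

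The method was tested on simulated data with the array design and 19938 genes, of which 200 were changed in each of 5 runs. A change of 0.5 on the log2 scale was recovered for 51.64% of genes in PAC at 3 weeks and 48.96% in TAC, and a change of 1 for 98.51% and 99.1%. False calls were 4.66% and 5.64% of the calls. A shift of 0.3 in a whole list was called in 10 of 10 runs, and 3 of 290 unshifted list tests were called. In these runs the simulated genes varied independently of each other. The list rates therefore do not cover correlated genes, and the estimated correlation of the matrix list in the real data was 0.745. Agreement of changes that share the sham RV arrays was checked against 100 simulated sets of unchanged groups, and with each PAC time given a different sham RV array. Replicate pairing was checked with the correlation of deviations between groups. Probe sets of the 1621 and 12146 groups were checked for calls but not otherwise analysed here.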

Results

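Right ventricles were compared between sham mice and mice with a clipped pulmonary artery (PAC) at 1, 3 and 6 weeks, and left ventricles between sham mice and mice with a constricted aorta (TAC) at 3 weeks, with n = 2 arrays per group. The study's title asks for genes enriched in the right heart under outflow obstruction, which the comparisons of PAC with sham RV, of chambers and of PAC with TAC address. All changes below are log2 differences ± the limma standard error, levels are means ± SD, and adjusted p is from limma for genes and from camera for gene lists. Of the largest changes named in each comparison, all arrays on 1 side lay above all on the other. Between 2 groups an exact permutation test of 2 against 2 arrays gives such a separation p = 0.33. The mean of the 3 PAC times sets the PAC arrays of all times against 2 sham RV arrays, and no exact p was computed for it. For the interaction the separation was not required, and no gene passed there. The p-values measure the spread between these samples, since the labels do not state that arrays came from separate animals. The only sham arrays are from 3 weeks, so the 1 and 6 week comparisons also differ in age and time since operation.

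At 3 weeks of PAC the right ventricle carried a load and matrix programme. Nppa, which encodes atrial natriuretic peptide and is a marker of wall stress, rose by 2.49 ± 0.38 (13.32 ± 0.38 against 10.83 ± 0.21 in sham, 5.6-fold, adjusted p = 0.018). Nppb rose by 1.99 ± 0.42 (adjusted p = 0.033), the slow myosin gene Myh7 by 1.80 ± 0.42 (adjusted p = 0.040) and skeletal actin Acta1 by 2.01 ± 0.31 (adjusted p = 0.018). The adult myosin gene Myh6 did not pass, at -0.08 ± 0.07 (adjusted p = 0.49), and its level lay between 13.67 and 13.8 on all arrays, near the highest value of 14.78. The largest increase was in Cilp, a cartilage and fibrosis matrix gene (3.20 ± 0.57, 9.17-fold, adjusted p = 0.025). It was followed by Postn, a product of activated fibroblasts (3.12 ± 0.51, 8.7-fold, adjusted p = 0.020), and the atrial light chain Myl4 (2.71 ± 0.66, adjusted p = 0.043). Sfrp2, a secreted Wnt modulator, rose by 2.15 ± 0.55, Aspn by 2.12 ± 0.29, Itgbl1 by 2.09 ± 0.33, Mfap5 by 2.07 ± 0.45, Col14a1 by 2.05 ± 0.38 and Col8a1 by 2.04 ± 0.46. The largest decreases were in the methyltransferase Inmt (-1.26 ± 0.31, adjusted p = 0.046), the carboxylesterase Ces1d (-1.19 ± 0.28), the enkephalin precursor Penk (-1.12 ± 0.21, adjusted p = 0.027) and Acsm5 (-0.98 ± 0.19). Tlcd4 (-0.96 ± 0.12, adjusted p = 0.017), the phosphorylase kinase subunit Phkg1 (-0.93 ± 0.14), the iron exporter Slc40a1 (-0.88 ± 0.19), Lvrn (-0.88 ± 0.18) and the chemokine Ccl11 (-0.84 ± 0.11) also fell. Among patterning factors Hand1 (-0.30 ± 0.11, adjusted p = 0.11), Hand2 (-0.32 ± 0.09, adjusted p = 0.062) and Tbx5 (-0.27 ± 0.11, adjusted p = 0.15) did not pass.

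**Figure D1:**
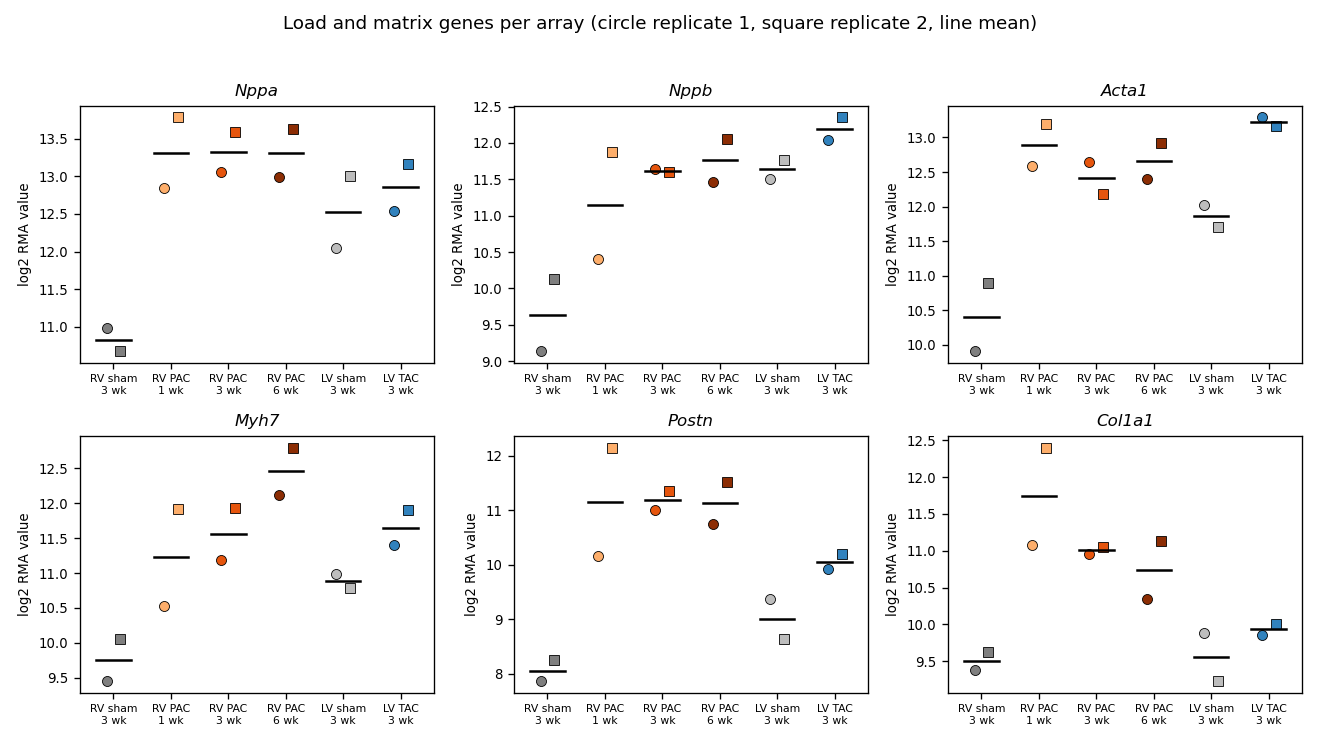
Level of Nppa, Nppb, Acta1, Myh7, Postn and Col1a1 on each array by group, as log2 expression, with circles for replicate 1, squares for replicate 2 and lines for means of n = 2 arrays. Nppa lies at 13.32 ± 0.38 in PAC at 3 weeks and 10.83 ± 0.21 in sham RV.

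Of the 58 extracellular matrix genes 22 rose and 0 fell at 3 weeks of PAC (43 higher adjusted over the list alone, median 0.93), among them Cilp, Postn, Mfap5 and Col14a1. The camera test gave adjusted p = 2e-19, and adjusted p = 0.40 with an estimated correlation. Of 19 fibroblast markers 10 rose and 0 fell (14 higher adjusted over the list alone, median 0.62). Lum (1.54 ± 0.21), Meox1 (1.67 ± 0.36) and Col1a2 (1.51 ± 0.36) were among them (camera adjusted p = 4.1e-08, adjusted p = 0.40 with an estimated correlation). Of 39 TGF-beta and BMP pathway genes 5 rose and 0 fell (8 higher and 1 lower adjusted over the list alone, median 0.23). Fstl1 rose by 1.74 ± 0.30, the ligand Tgfb3 by 1.24 ± 0.29, Skil by 0.88 ± 0.23 and the receptor Tgfbr1 by 0.77 ± 0.17 (camera adjusted p = 0.00016, adjusted p = 0.40 with an estimated correlation). Of 23 endothelial markers 6 rose and 0 fell (15 higher and 1 lower adjusted over the list alone, median 0.33), with Sox17 at 0.71 ± 0.15, Esam at 0.59 ± 0.13, the VEGF receptor Kdr at 0.43 ± 0.10 and Egfl7 at 0.38 ± 0.09. For this list camera gave adjusted p = 3.8e-09, and adjusted p = 0.28 with an estimated correlation. Of 18 load-responsive cardiomyocyte genes 7 rose and 0 fell (10 higher adjusted over the list alone, median 0.75, camera adjusted p = 1.7e-05, adjusted p = 0.40 with an estimated correlation). Smooth muscle and pericyte markers split, with 5 of 18 higher and 1 lower (6 and 2 adjusted over the list alone, median 0.09). Vtn rose by 0.74 ± 0.12, the actin gene Acta2 by 0.72 ± 0.16, Higd1b by 0.67 ± 0.12 and Pdgfrb by 0.55 ± 0.10 (camera adjusted p = 0.021, adjusted p = 0.28 with an estimated correlation, 0.17 without sham RV array 1, 0.25 with loess scaling and 0.22 without genes below the median level). Without PAC 3 week array 2 the median of the TGF-beta and BMP list was 0.13, of the endothelial list 0.21 and of the smooth muscle list 0.05, the last being 0.19 without sham RV array 2.

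Fatty acid oxidation and respiratory chain genes were lower as lists, and glycolysis genes higher. Of 33 fatty acid oxidation genes 2 fell and 0 rose at 3 weeks (4 lower adjusted over the list alone, median -0.26), Etfb by -0.53 ± 0.12 and the metabolic nuclear receptor Esrra by -0.42 ± 0.10. At the preset correlation camera gave adjusted p = 0.00027, and adjusted p = 0.56 with an estimated correlation. Of 55 respiratory chain and citrate cycle genes 3 fell and 0 rose (4 lower adjusted over the list alone, median -0.12), namely Ndufb8 (-0.51 ± 0.11), Cox8b (-0.47 ± 0.10) and Cox4i1 (-0.42 ± 0.09). As a list they had camera adjusted p = 0.0031, with adjusted p = 0.62 with an estimated correlation and 0.083 without sham RV array 1. In the glycolysis and glucose uptake list 2 of 21 genes rose (2 adjusted over the list alone, median 0.18), the phosphofructokinases Pfkp (1.25 ± 0.23, adjusted p = 0.025) and Pfkl (0.50 ± 0.09). The glucose transporter Slc2a1 stood at 0.51 ± 0.16 (adjusted p = 0.072) and did not pass (camera adjusted p = 0.0038, adjusted p = 0.28 with an estimated correlation, 0.13 without genes below the median level). The glycolysis median was 0.09 without PAC 3 week array 2.

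Cell cycle genes were still raised at 3 weeks, with 5 of 47 higher and 0 lower (12 and 1 adjusted over the list alone, median 0.27). Prc1 rose by 1.29 ± 0.26, Top2a by 1.07 ± 0.24, Ect2 by 1.04 ± 0.23 and Ccnd2 by 0.62 ± 0.12 (camera adjusted p = 3.5e-07, adjusted p = 0.47 with an estimated correlation). Of 34 macrophage and myeloid markers 0 passed by limma at 3 weeks and 0 adjusted over the list alone (median 0.23), with Ctss at 0.71 ± 0.30, Ccr2 at 0.62 ± 0.31, Cd14 at 0.57 ± 0.17 and Cd74 at -0.53 ± 0.17. Tested with camera the list had adjusted p = 0.015, with adjusted p = 0.62 with an estimated correlation, 0.42 without PAC 3 week array 2, 0.051 without sham RV array 1, 0.10 with loess scaling and 0.51 without genes below the median level. Of 12 atrial markers, 6 of which stand on another list, 3 rose and 0 fell (5 and 1 adjusted over the list alone, median 0.68). These were Myl4, Nppa and Dkk3 (1.94 ± 0.50, adjusted p = 0.047), while Myl7 stood at 2.85 ± 0.80 (adjusted p = 0.060). In camera the list reached adjusted p = 0.0053, with adjusted p = 0.47 with an estimated correlation, 0.058 without PAC 3 week array 2 and 0.30 without genes below the median level. Bmp10, which is made by atrial muscle, was 8.79 on PAC 3 week array 2 and 4.52 on array 1, so this marker was high on the array whose removal ends the call.

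In all, 1148 genes passed at 3 weeks of PAC, 642 higher and 506 lower, and 79 of them changed at least 2-fold. Of the 1621 probe sets with several genes 77 passed, and of the 12146 unlisted probe sets 0 passed by limma. The gene count rests on few arrays. It was 3 without PAC 3 week array 2, 51 without sham RV array 1 and 3 without sham RV array 2, and of 52 named genes 0, 1 and 0 kept the call. Leaving out an array of another group also moved it, to 2070 without either PAC 1 week array, 273 without either TAC array and 535 without either sham LV array. With PAC 1 week array 2 and sham LV array 2 both left out, a choice made after seeing the data, it was 1545, and with loess scaling 535, of which 478 were shared. Without genes below the median level 1212 were higher and 375 lower, a share of increases of 76.4% against 55.9%.

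At 1 week of PAC the same load genes were high, and cell cycle genes rose. Nppa rose by 2.48 ± 0.38 (adjusted p = 0.0073), Acta1 by 2.49 ± 0.31 (12.9 ± 0.44 against 10.4 ± 0.70, 5.63-fold, adjusted p = 0.0034), Nppb by 1.5 ± 0.42 (adjusted p = 0.036) and Myh7 by 1.47 ± 0.42 (adjusted p = 0.039). Myh6 (-0.07 ± 0.07, adjusted p = 0.51) did not pass. The largest increases were in atrial muscle genes, with Bmp10 at 5.06 ± 1.03 (9.52 ± 1.37 against 4.46 ± 0.25, adjusted p = 0.015), Myl7 at 3.26 ± 0.80 (adjusted p = 0.025) and Myl4 at 3.12 ± 0.66. The sham level of Bmp10, like the 1 week level of Mmrn1 below, lies under the median of unlisted probe sets (5.65 to 5.79 by array), so neither change is read as an exact fold. Matrix genes and their regulators came next: Postn (3.09 ± 0.51, adjusted p = 0.0081), the protease inhibitor Timp1 (2.75 ± 0.71, adjusted p = 0.029), fibronectin Fn1 (2.41 ± 0.43), tenascin Tnc (2.37 ± 0.74) and the collagen cross-linking enzyme Lox (2.37 ± 0.64). The endothelial matrix gene Mmrn1 fell to a level near background, with a fitted change of -3.39 ± 0.24 (3.96 ± 0.11 against 7.34 ± 0.09, adjusted p = 0.00065). Among other genes that fell were Inmt (-2.99 ± 0.31, adjusted p = 0.0029) and Penk (-2.28 ± 0.21). Amylase Amy1 (-1.55 ± 0.22), Acsm5 (-1.25 ± 0.19), complement C7 (-1.16 ± 0.22), Prkcq (-1.14 ± 0.13), Hsd11b1 (-1.11 ± 0.14), Slc15a2 (-1.09 ± 0.28) and the potassium channel subunit Kcnv2 (-1.08 ± 0.26) fell too. The patterning factors Hand1 (-0.45 ± 0.11, adjusted p = 0.026) and Hand2 (-0.45 ± 0.09, adjusted p = 0.015) fell, and Tbx5 (-0.05 ± 0.11, adjusted p = 0.79) did not pass.

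Of 47 cell cycle genes 30 rose and 0 fell at 1 week (40 higher adjusted over the list alone, median 0.64). The mitotic genes Prc1 (2.31 ± 0.26), Top2a (2.25 ± 0.24), Ect2 (2.08 ± 0.23) and Kif11 (2.02 ± 0.25) led the list (camera adjusted p = 2.9e-21, adjusted p = 0.39 with an estimated correlation). Of 34 macrophage and myeloid markers 15 rose and 0 fell (24 higher adjusted over the list alone, median 0.59), with the monocyte receptor Ccr2 at 1.39 ± 0.31 (adjusted p = 0.020), Itgam at 1.23 ± 0.27, Ctss at 1.12 ± 0.30 and Cx3cr1 at 0.95 ± 0.18. Camera gave an adjusted p of 3.3e-08, and adjusted p = 0.39 with an estimated correlation. Of 58 extracellular matrix genes 35 rose and 1 fell (39 and 1 adjusted over the list alone, median 1.03, camera adjusted p = 7.9e-17, adjusted p = 0.39 with an estimated correlation). Of 19 fibroblast markers 10 rose and 0 fell (13 higher adjusted over the list alone, median 0.56). Col1a1 rose by 2.23 ± 0.38 (adjusted p = 0.0088), Col1a2 by 1.97 ± 0.36, Mfap5 by 1.79 ± 0.45 and Cthrc1 by 1.56 ± 0.47 (camera adjusted p = 1.9e-05, adjusted p = 0.39 with an estimated correlation). Of 18 load-responsive cardiomyocyte genes 11 rose and 0 fell (12 higher adjusted over the list alone, median 1.06, camera adjusted p = 2.3e-07, adjusted p = 0.39 with an estimated correlation). Of 23 endothelial markers 7 rose and 0 fell (10 and 1 adjusted over the list alone, median 0.27). The apelin receptor Aplnr rose by 1.05 ± 0.19, its ligand Apln by 0.43 ± 0.13, Erg by 0.38 ± 0.09 and Tie1 by 0.38 ± 0.08 (camera adjusted p = 0.00061, adjusted p = 0.39 with an estimated correlation, 0.081 with loess scaling). Of 12 atrial markers 6 rose and 0 fell (6 adjusted over the list alone, median 1.22, camera adjusted p = 0.00026, adjusted p = 0.39 with an estimated correlation, 0.065 without genes below the median level). Without PAC 1 week array 2 the medians were 0.41 for cell cycle, 0.28 for macrophage, 0.67 for extracellular matrix, 0.62 for load-responsive and 0.77 for atrial genes, and camera still called these lists.

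**Figure D2:**
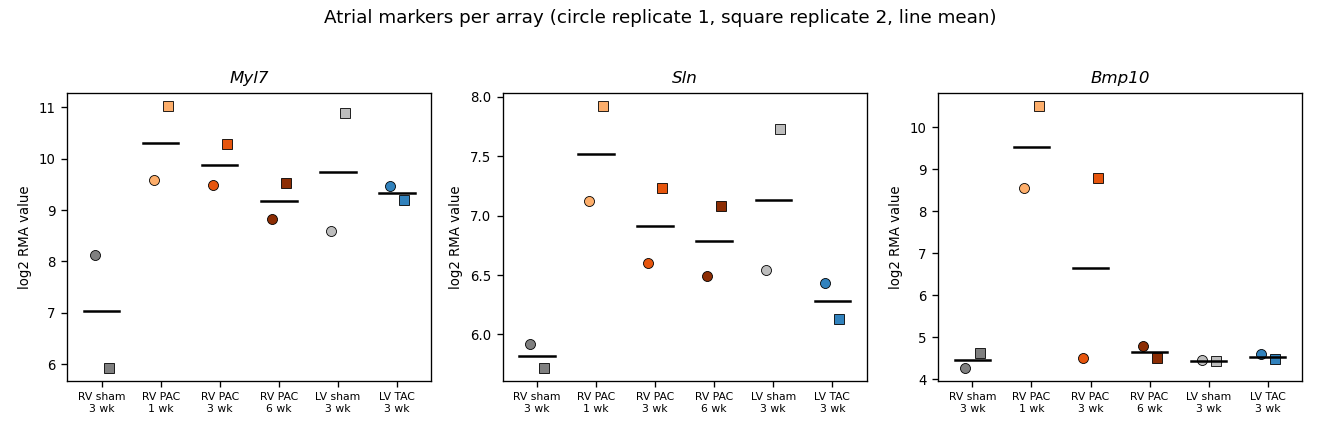
Level of the atrial markers Myl7, Sln and Bmp10 on each array by group, as log2 expression, with circles for replicate 1, squares for replicate 2 and lines for means of n = 2 arrays. Bmp10 is 8.55 and 10.5 at 1 week of PAC, 8.79 on PAC 3 week array 2 and 4.28 to 4.79 on the other arrays.

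Several other lists called at 1 week depend on single arrays. Of 39 TGF-beta and BMP pathway genes 5 rose and 1 fell (10 and 2 adjusted over the list alone, median 0.19), with Fstl1 at 1.87 ± 0.30, Tgfb3 at 1.00 ± 0.29, Tgfbr1 at 0.86 ± 0.17 and Tgfb1 at 0.60 ± 0.16. For this list camera gave adjusted p = 0.0058, with adjusted p = 0.47 with an estimated correlation and 0.15 without PAC 1 week array 2. Of 33 fatty acid oxidation genes 5 fell and 0 rose (5 adjusted over the list alone, median -0.30), with Acaa2 at -0.61 ± 0.16, Mlycd at -0.51 ± 0.13, Etfb at -0.46 ± 0.12 and Acads at -0.37 ± 0.11. At the preset correlation camera gave adjusted p = 0.00026, with adjusted p = 0.53 with an estimated correlation and 0.18 without PAC 1 week array 2. Of 55 respiratory chain genes 3 fell (3 adjusted over the list alone, median -0.12), namely Cox8b (-0.42 ± 0.10), Cox4i1 (-0.39 ± 0.09) and Sdhc (-0.39 ± 0.09). As a list they had camera adjusted p = 0.015, with adjusted p = 0.65 with an estimated correlation, 0.53 without PAC 1 week array 2 and 0.17 without sham RV array 1. Epicardial and mesothelial markers had 3 of 13 higher and 0 lower (4 adjusted over the list alone, median 0.35), with the retinoic acid enzyme Aldh1a2 at 1.42 ± 0.37, Msln at 0.91 ± 0.24 and Muc16 at 0.91 ± 0.26. Tested with camera the list had adjusted p = 0.025, with adjusted p = 0.40 with an estimated correlation, 0.30 without PAC 1 week array 1 and 0.11 without sham RV array 2. Of 28 immediate early and heat shock genes 3 rose and 1 fell (median 0.15), with Myc at 0.94 ± 0.21, Btg2 at 0.75 ± 0.20, Jun at 0.48 ± 0.12 and Fosb at -0.56 ± 0.14. In camera the list reached adjusted p = 0.029, with adjusted p = 0.54 with an estimated correlation, 0.64 without PAC 1 week array 2 and 0.17 without sham RV array 1. Of 25 oxidative stress genes 6 rose and 3 fell (7 and 3 adjusted over the list alone, median 0.21), with the metallothionein Mt2 at 2.19 ± 0.48, Hmox1 at 1.00 ± 0.24, Cybb at 0.80 ± 0.22 and Gpx1 at 0.78 ± 0.18. Camera gave an adjusted p of 0.042, with adjusted p = 0.42 with an estimated correlation, 0.18 without PAC 1 week array 2 and 0.10 without sham RV array 2. Loess scaling ended the calls of the TGF-beta and BMP (adjusted p = 0.066), immediate early (0.099) and oxidative stress lists (0.51). Leaving out genes below the median level ended these calls too (0.065, 0.51 and 0.85), and that of the epicardial list (0.53). Without PAC 1 week array 1 the medians were 0.30 for TGF-beta and BMP, -0.48 for fatty acid oxidation and 0.37 for immediate early genes, the last being 0.27 without sham RV array 2. The epicardial median was 0.60 without PAC 1 week array 2 and 0.63 without sham RV array 1.

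In all, 3675 genes passed at 1 week of PAC, 1909 higher and 1766 lower, with 210 changed at least 2-fold. The count was 317 without PAC 1 week array 2, 1090 without sham RV array 1 and 227 without sham RV array 2, and 21, 27 and 13 of 70 named genes kept the call. With PAC 1 week array 2 and sham LV array 2 left out, a choice made after seeing the data, 167 genes passed. Loess scaling gave 2174 genes, 1363 higher and 811 lower, so the share of increases moved from 51.9% to 62.7%. Without genes below the median level it was 74.3% (2001 higher and 693 lower), and a fit to only the arrays compared gave 89 genes. The median change by decile of gene level ran from -0.22 among dim genes to 0.11 among bright ones, so the split depends on level.

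At 6 weeks of PAC matrix genes and slow myosin stayed high. The thrombospondin Thbs4 rose by 4.01 ± 0.80 (16.1-fold, adjusted p = 0.020), Cilp by 3.75 ± 0.57 (adjusted p = 0.010), Postn by 3.08 ± 0.51 (adjusted p = 0.012) and Myh7 by 2.70 ± 0.42 (12.46 ± 0.49 against 9.76 ± 0.43, 6.51-fold, adjusted p = 0.010). Fibromodulin Fmod (2.61 ± 0.44), Fibin (2.60 ± 0.34, adjusted p = 0.0071), Comp (2.51 ± 0.40), Thbs1 (2.44 ± 0.59) and Col12a1 (2.42 ± 0.58) followed. Nppa rose by 2.47 ± 0.38 (adjusted p = 0.010), Acta1 by 2.26 ± 0.31 (adjusted p = 0.0075) and Nppb by 2.12 ± 0.42 (adjusted p = 0.019). Among genes that fell were Efemp1 (-1.75 ± 0.32, adjusted p = 0.016), Ces1d (-1.60 ± 0.28), the alcohol dehydrogenase Adh1 (-1.56 ± 0.23, adjusted p = 0.0087), Inmt (-1.40 ± 0.31) and Penk (-1.37 ± 0.21). Lgi1 (-1.35 ± 0.34), Lrrn4 (-1.31 ± 0.36), Acsm5 (-1.23 ± 0.19), the vessel-stabilising ligand Angpt1 (-1.21 ± 0.17, adjusted p = 0.0081) and the thioesterase Acot1 (-1.14 ± 0.29) fell as well. Tbx5 fell by -0.53 ± 0.11 (adjusted p = 0.024). Hand1 (-0.07 ± 0.11, adjusted p = 0.71), Hand2 (-0.23 ± 0.09, adjusted p = 0.12) and Myh6 (-0.10 ± 0.07, adjusted p = 0.39) did not pass.

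Of 58 extracellular matrix genes 23 rose and 0 fell at 6 weeks (38 higher adjusted over the list alone, median 0.85, camera adjusted p = 3e-17, adjusted p = 0.37 with an estimated correlation). Of 39 TGF-beta and BMP pathway genes 9 rose and 0 fell (16 and 4 adjusted over the list alone, median 0.35), including the TGF-beta target Ccn2 (1.98 ± 0.49), Fstl1 (1.5 ± 0.30), Tgfb2 (1.32 ± 0.33) and Tgfb3 (1.17 ± 0.29). For this list camera gave adjusted p = 6.1e-05, and adjusted p = 0.37 with an estimated correlation. Of 19 fibroblast markers 7 rose and 0 fell (10 and 1 adjusted over the list alone, median 0.58), with Meox1 at 1.99 ± 0.36, Mfap5 at 1.95 ± 0.45, Pi16 at 1.25 ± 0.21 and Lum at 1.07 ± 0.21 (camera adjusted p = 7.7e-06, adjusted p = 0.37 with an estimated correlation). Of 18 load-responsive cardiomyocyte genes 8 rose and 0 fell (12 higher adjusted over the list alone, median 1.19, camera adjusted p = 3.2e-07, adjusted p = 0.37 with an estimated correlation). Of 23 endothelial markers 22 had a change above 0 at 6 weeks, 2 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.17), with Aplnr at 0.74 ± 0.19, nitric oxide synthase Nos3 at 0.31 ± 0.08 and Tal1 at -0.29 ± 0.08. At the preset correlation camera gave adjusted p = 0.00023, and adjusted p = 0.37 with an estimated correlation. Of 33 fatty acid oxidation genes 4 fell and 0 rose (13 lower adjusted over the list alone, median -0.25), among them Acot1, Acaa2 (-0.71 ± 0.16), Etfb (-0.58 ± 0.12) and Mlycd (-0.48 ± 0.13). As a list they had camera adjusted p = 0.00023, and adjusted p = 0.51 with an estimated correlation. Of 55 respiratory chain genes 7 fell and 0 rose (7 adjusted over the list alone, median -0.12), with Ndufb8 at -0.49 ± 0.11 and Sdhc at -0.48 ± 0.09. Tested with camera the list had adjusted p = 0.0012, with adjusted p = 0.60 with an estimated correlation and 0.051 without sham RV array 1. Glycolysis and glucose uptake genes had 3 of 21 higher and 0 lower (6 and 2 adjusted over the list alone, median 0.13), namely Pfkp (1.66 ± 0.23), Slc2a1 (0.60 ± 0.16) and Pfkl (0.49 ± 0.09). In camera the list reached adjusted p = 0.013, and adjusted p = 0.37 with an estimated correlation. With loess scaling the endothelial and glycolysis calls ended (adjusted p = 0.080 and 0.071), and the glycolysis call also without genes below the median level (0.37). Without PAC 6 week array 2 the medians were 0.18 for TGF-beta and BMP, 0.37 for fibroblast and -0.07 for respiratory chain genes, and the glycolysis median was 0.08 without sham RV array 2.

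Cell cycle genes were near sham at 6 weeks, with 2 of 47 higher and 1 lower (2 and 1 adjusted over the list alone, median 0.13). The cyclins Ccnd2 (0.65 ± 0.12) and Ccnd1 (0.57 ± 0.10) rose and Cenpf (-0.99 ± 0.22) fell. Camera gave an adjusted p of 0.0086, with adjusted p = 0.64 with an estimated correlation, 0.088 without PAC 6 week array 1, 0.051 without sham RV array 1 and 0.27 without genes below the median level. Macrophage markers were not called (median 0.03, camera adjusted p = 0.70), and neither were atrial markers (median 0.15, camera adjusted p = 0.080). Immediate early and heat shock genes were called higher (2 of 28 higher and 0 lower, median 0.20, camera adjusted p = 0.0012, adjusted p = 0.41 with an estimated correlation). Oxidative stress genes were called at 6 weeks (median 0.21, camera adjusted p = 0.020) and 3 weeks (0.19, 0.036), with adjusted p = 0.39 and 0.47 with an estimated correlation. Both oxidative stress calls ended without sham RV array 2. Epicardial and mesothelial markers had 2 of 13 lower and 0 higher (3 adjusted over the list alone, median -0.46, camera adjusted p = 0.048, adjusted p = 0.43 with an estimated correlation), namely Efemp1 and Lrrn4. That call ended with loess scaling (0.058), without genes below the median level (0.20), and without either sham LV array (0.056), either PAC 3 week array (0.067), PAC 6 week array 2 (0.088) or sham RV array 1 (0.21). A total of 1844 genes passed at 6 weeks, 1101 higher and 743 lower, with 117 changed at least 2-fold. The count was 3 without PAC 6 week array 2, 527 without sham RV array 1 and 99 without sham RV array 2, and 1, 18 and 7 of 68 named genes kept the call. It was 1019 without either TAC array, 1223 without either sham LV array and 2043 without PAC 1 week array 2 and sham LV array 2, the last chosen after seeing the data. A fit to only the arrays compared gave 1020 genes, and without genes below the median level 71.6% of calls were higher against 59.7%.

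**Figure D3:**
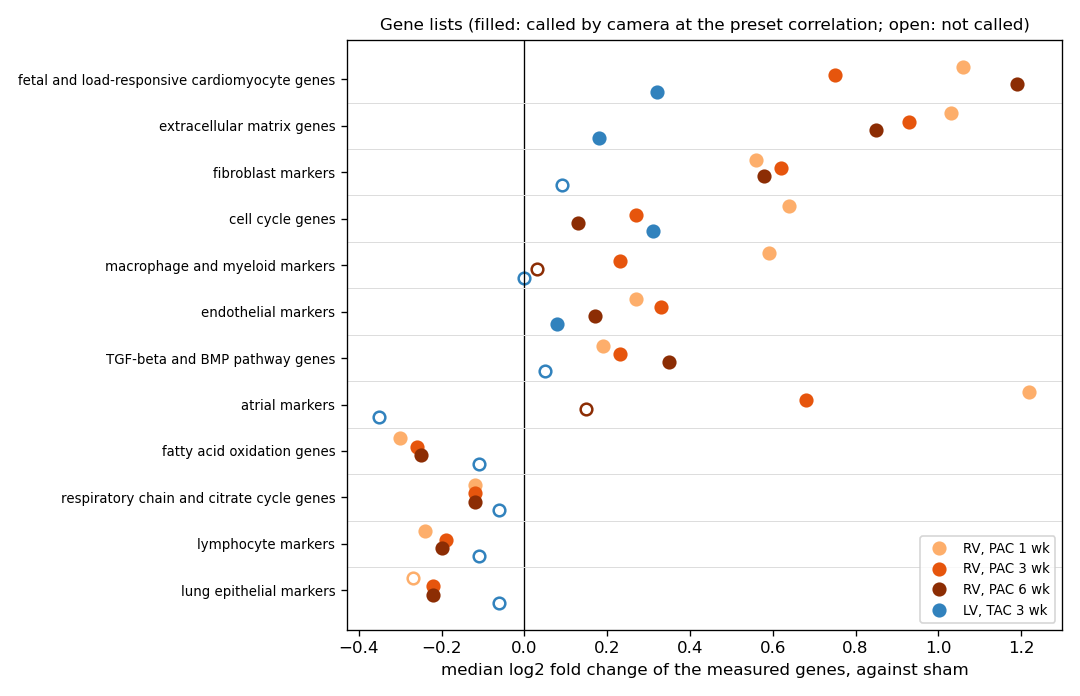
Median change of 12 gene lists against sham for PAC at 1, 3 and 6 weeks and TAC at 3 weeks, n = 2 arrays per group. Filled points were called by camera at the preset correlation and open points were not; extracellular matrix lies at 1.03, 0.93 and 0.85 in PAC and 0.18 in TAC.

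Over the mean of the 3 PAC times against sham RV the largest increases, which include atrial muscle genes although the atrial list was not called at 6 weeks (adjusted p = 0.080), were Postn (3.10 ± 0.42, adjusted p = 0.0036), Cilp (3.04 ± 0.47), Myl7 (2.75 ± 0.65), Myl4 (2.64 ± 0.54) and Nppa (2.48 ± 0.31, adjusted p = 0.0033). Timp1 (2.29 ± 0.58), Acta1 (2.25 ± 0.26, adjusted p = 0.0027), Col8a1 (2.20 ± 0.37), Fibin (2.00 ± 0.28), Aspn (1.99 ± 0.24), Myh7 (1.99 ± 0.34) and Nppb (1.87 ± 0.34) rose too. Inmt (-1.88 ± 0.26), Penk (-1.59 ± 0.17, adjusted p = 0.0021), BC023105 (-1.51 ± 0.46), Retnla (-1.40 ± 0.43), Ces1d (-1.24 ± 0.23) and Efemp1 (-1.20 ± 0.26) fell most. They were followed by Acsm5 (-1.16 ± 0.16), Amy1 (-1.11 ± 0.18), Slc40a1 (-1.02 ± 0.16) and Lgals4 (-0.96 ± 0.25). Hand2 (-0.33 ± 0.07, adjusted p = 0.014) and Tbx5 (-0.28 ± 0.09, adjusted p = 0.049) fell, while Hand1 (-0.27 ± 0.09, adjusted p = 0.051) and Myh6 (-0.08 ± 0.06, adjusted p = 0.32) did not pass. Of 58 extracellular matrix genes 42 rose and 0 fell (45 and 1 adjusted over the list alone, median 0.95, camera adjusted p = 4.6e-19, adjusted p = 0.33 with an estimated correlation). Of 33 fatty acid oxidation genes 11 fell and 0 rose (14 lower adjusted over the list alone, median -0.27, camera adjusted p = 0.00012, adjusted p = 0.49 with an estimated correlation). In all, 4941 genes passed, 2426 higher and 2515 lower, and 116 changed at least 2-fold. The count was 1520 without sham RV array 1, 296 without sham RV array 2, 3140 without PAC 3 week array 2 and 3010 without PAC 6 week array 2. It was 3045 with loess scaling and 3502 without PAC 1 week array 2 and sham LV array 2, the latter chosen after seeing the data, when 70 of 77 named genes kept the call. A fit to only the arrays compared gave 2914 genes, and without genes below the median level 71.2% of calls were higher against 49.1%.

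Shared genes between the PAC times were many. A set of 405 genes was higher and 234 lower at all 3 times. Between 1 and 3 weeks 532 genes were higher in both against 61.5 expected from the separate counts, and 378 lower against 44.8. Between 1 and 6 weeks these were 806 against 105.4 and 471 against 65.8, and between 3 and 6 weeks 464 against 35.5 and 277 against 18.9. No gene passed in opposite directions. Over 19938 genes the changes correlated with r = 0.845, 0.795 and 0.874 (rank correlation 0.844, 0.821 and 0.856). All 3 comparisons share the same sham RV arrays, and unchanged groups compared with a shared sham gave r = 0.5 in simulation. Apart from that sham the simulated groups were independent, so a batch shared by PAC arrays is not part of the simulated value. The covariances of 0.0799, 0.0775 and 0.0721 exceed the 0.0086 that the shared sham gives, and a test chosen after seeing the data gave each time a different sham RV array. The correlation was then 0.684 to 0.696 between 1 and 3 weeks, 0.632 to 0.665 between 1 and 6 weeks and 0.684 to 0.707 between 3 and 6 weeks, where the sham arrays add only what both have in common.

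Between 6 and 1 weeks of PAC cell cycle genes were lower and Mmrn1 higher. Mmrn1 was higher at 6 weeks by 3.70 ± 0.24 (7.66 ± 0.35 against 3.96 ± 0.11, adjusted p = 0.00026), with Cpxm2 (1.69 ± 0.20, adjusted p = 0.027) and Dct (1.33 ± 0.20). Prune2 (0.85 ± 0.12), Sncg (0.64 ± 0.09) and Golga4 (0.62 ± 0.09) were higher as well. Topoisomerase Top2a fell by -1.82 ± 0.24 (6.51 ± 0.19 against 8.33 ± 0.68, 3.54-fold lower, adjusted p = 0.039), the kinetochore gene Knl1 by -1.51 ± 0.21, the condensin gene Ncapg by -1.51 ± 0.21, Ccnb2 by -1.20 ± 0.16 and Ckap2 by -1.14 ± 0.16. Casq1, a skeletal calcium store protein, fell by -1.45 ± 0.22 (adjusted p = 0.046), Mest by -1.44 ± 0.19, H2ac4 by -1.04 ± 0.15, Epn3 by -0.95 ± 0.09 (adjusted p = 0.0086) and Pxdn by -0.85 ± 0.11. The load genes did not pass, with Nppa at 0.00 ± 0.38, Nppb at 0.62 ± 0.42, Myh7 at 1.24 ± 0.42 (adjusted p = 0.35) and Acta1 at -0.24 ± 0.31. Nor did Hand1 (0.38 ± 0.11, adjusted p = 0.26), Hand2 (0.22 ± 0.09), Tbx5 (-0.48 ± 0.11, adjusted p = 0.15) or Myh6 (-0.03 ± 0.07). Of 47 cell cycle genes 2 fell and 0 rose (36 lower and 1 higher adjusted over the list alone, median -0.60, camera adjusted p = 7.6e-38, adjusted p = 0.22 with an estimated correlation). Of 34 macrophage markers 0 passed by limma and 23 were lower adjusted over the list alone (median -0.53), with Ccr2 at -1.40 ± 0.31 and Itgam at -1.07 ± 0.27. For this list camera gave adjusted p = 3.7e-20, and adjusted p = 0.23 with an estimated correlation. Of 13 epicardial and mesothelial markers 0 passed by limma and 9 were lower and 1 higher adjusted over the list alone (median -1.05). Upk1b stood at -2.31 ± 0.40, Lrrn4 at -1.67 ± 0.36, Aldh1a2 at -1.63 ± 0.37 and Msln at -1.35 ± 0.24 (camera adjusted p = 4.3e-10, adjusted p = 0.22 with an estimated correlation). Without PAC 1 week array 2 the cell cycle median was -0.33 and the macrophage median -0.29, and camera still called both.

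The count of single genes between 6 and 1 weeks was small and unstable. It was 19 genes, 7 higher and 12 lower, with 12 changed at least 2-fold. Of all genes 1944 had an unadjusted p below 0.05 in the moderated model, against 997 expected by chance, a count not backed by an exact test. It was 488 without PAC 1 week array 1, 14 without array 2, 4 without either PAC 3 week array, 37 without PAC 6 week array 1 and 1 without array 2. Without either TAC or either sham LV array it was 2, without either sham RV array 3, and without PAC 1 week array 2 and sham LV array 2, chosen after seeing the data, 5. With a block for replicate number it was 11, and 9 of 17 named genes kept the call. It was 32 without genes below the median level, 83 with the trended and robust prior and 1 in a fit to only the arrays compared.

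In the left ventricle at 3 weeks of TAC no gene passed in limma. Acta1 stood at 1.36 ± 0.31 (13.22 ± 0.1 against 11.87 ± 0.21), Myh7 at 0.76 ± 0.42, Nppb at 0.56 ± 0.42 and Nppa at 0.33 ± 0.38. Sham LV already had a high Nppa level of 12.52 ± 0.67, with 13.0 on array 2 and 12.05 on array 1, and Myl7 was 10.9 on array 2 and 8.59 on array 1. Tbx5 (-0.42 ± 0.11, adjusted p = 0.98), Hand1 (-0.12 ± 0.11), Hand2 (0.05 ± 0.09) and Myh6 (-0.08 ± 0.07) did not pass. The genes with the smallest p did not pass either: Aqp8 (0.78 ± 0.13), B3galt2 (0.67 ± 0.11), Fscn1 (0.64 ± 0.11), Tceal6 (-0.60 ± 0.10, adjusted p = 0.65) and Ccl11 (-0.62 ± 0.11, adjusted p = 0.89). Camera called 5 of 30 lists at the preset correlation, while fry called 0 (cell cycle and load lists adjusted p = 0.59, matrix 0.79) and 0 held with an estimated correlation. In PAC at 3 weeks fry did not call these 3 lists either (cell cycle adjusted p = 0.19, load 0.085, matrix 0.076). There it kept 8 of the 17 lists that camera called. Of 47 cell cycle genes 0 passed by limma and 0 adjusted over the list alone (median 0.31), with Prc1 at 1.01 ± 0.26, Top2a at 0.98 ± 0.24, Ccna2 at 0.84 ± 0.27 and Ect2 at 0.82 ± 0.23. At the preset correlation camera gave adjusted p = 4.3e-18, and adjusted p = 0.78 with an estimated correlation. Of 18 load-responsive genes 0 passed by limma and 2 were higher adjusted over the list alone (median 0.32), with Mybpc2 at 0.92 ± 0.20 and Xirp2 at 0.60 ± 0.26 (camera adjusted p = 2.9e-06, adjusted p = 0.78 with an estimated correlation). Of 58 extracellular matrix genes 0 passed by limma and 0 adjusted over the list alone (median 0.18), with Cilp at 1.33 ± 0.57, Postn at 1.05 ± 0.51 and Col8a1 at 0.96 ± 0.46. As a list they had camera adjusted p = 1.4e-05, with adjusted p = 0.80 with an estimated correlation and 0.081 without sham LV array 2. Endothelial markers had 0 of 23 past the threshold by limma (median 0.08), with Aplnr at 0.65 ± 0.19 and Cldn5 at 0.25 ± 0.09. Tested with camera the list had adjusted p = 0.0012, with adjusted p = 0.78 with an estimated correlation and 0.070 without sham LV array 1. Calcium handling and ion channel genes were lower as a list (median -0.08, camera adjusted p = 0.024, adjusted p = 0.80 with an estimated correlation), a call that ended without TAC array 2 (0.33) or sham LV array 1 (0.16). Fatty acid oxidation genes were not called (median -0.11, camera adjusted p = 0.11). The cell cycle median was 0.20 without TAC array 2, the endothelial median 0.05 without TAC array 1 and the matrix median 0.29 without sham LV array 1.

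In TAC 963 genes had a moderated limma p below 0.05, not an exact one, against 997 expected by chance. Fitting only the arrays compared gave 1757, and the trended and robust prior 925. The smallest adjusted p was 0.65, and over the alternatives it ranged from 0.0065 to 1. A single gene passed without sham LV array 1.

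Single genes differed between sham right and left ventricles, though the number that passed varied widely between settings. Wif1, a secreted Wnt antagonist, was higher in RV by 1.19 ± 0.13 (7.61 ± 0.24 against 6.42 ± 0.23, 2.28-fold, adjusted p = 0.019), as was the guidance ligand Slit2 (1.05 ± 0.13, adjusted p = 0.019). Prkcz (0.69 ± 0.11), an immunoglobulin kappa variable gene (0.62 ± 0.11), Grcc10 (0.61 ± 0.11), Krt86 (0.61 ± 0.09), Atp5e (0.60 ± 0.10) and Sort1 (0.54 ± 0.10) were higher in RV as well. Nrn1, a neuritin, was lower in RV by -2.12 ± 0.19 (6.16 ± 0.02 against 8.28 ± 0.14, 4.34-fold lower, adjusted p = 0.0063), and the sarcomere gene Myot by -1.20 ± 0.14 (8.9 ± 0.31 against 10.1 ± 0.03, adjusted p = 0.019). Zfp931 (-1.27 ± 0.15), Rida (-1.08 ± 0.14), Zfp758 (-0.93 ± 0.13), Fuca2 (-0.92 ± 0.11), Lrrcc1 (-0.92 ± 0.13), Sdhaf4 (-0.91 ± 0.12), C1galt1c1 (-0.87 ± 0.12) and Chac2 (-0.86 ± 0.13) were lower too. Nppb (-2.00 ± 0.42, adjusted p = 0.057), Nppa (-1.69 ± 0.38, adjusted p = 0.066), Acta1 (-1.46 ± 0.31, adjusted p = 0.061) and Myh7 (-1.13 ± 0.42, adjusted p = 0.17) did not pass. Hand2 (0.34 ± 0.09, adjusted p = 0.090), Hand1 (0.06 ± 0.11), Tbx5 (0.12 ± 0.11) and Myh6 (0.01 ± 0.07) did not pass. Of 18 load-responsive genes 0 passed by limma and 9 were lower in RV adjusted over the list alone (median -0.54, camera adjusted p = 0.0016, adjusted p = 0.85 with an estimated correlation, 0.087 without genes below the median level). Of 66 Wnt pathway genes 1 was higher in RV, Wif1, and 5 were higher adjusted over the list alone (median 0.17). Dkk3 (-0.90 ± 0.50), Sfrp2 (-0.62 ± 0.55) and Frzb (-0.57 ± 0.43) pointed the other way without passing (camera adjusted p = 0.00052, adjusted p = 0.045 with an estimated correlation).

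A total of 82 genes differed between sham chambers, 15 higher and 67 lower in RV, with 9 at least 2-fold apart. Loess scaling also gave 82, with 28 higher and 54 lower and 55 shared, so the share of genes higher in RV moved from 18.3% to 34.1%. The count was 132 without sham RV array 1, 5 without sham RV array 2, 4 without sham LV array 1 and 0 by limma without sham LV array 2, where 3279 genes had a moderated p below 0.05, not an exact one. It was 252 without either PAC 1 week array, 41 or 38 without a PAC 3 or 6 week array, 11 without a TAC array, 871 without genes below the median level, 723 with the trended and robust prior, 6 in a fit to only the arrays compared, 56 with a block for replicate number (5 of 20 named calls ended) and 0 by limma without PAC 1 week array 2 and sham LV array 2, the last chosen after seeing the data.

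Clipped right ventricle and constricted left ventricle at 3 weeks differed in 4 genes, all lower in the right: Nrn1 (-1.67 ± 0.19), Bex1 (-1.62 ± 0.18), Myot (-1.33 ± 0.14) and the galactosyltransferase B3galt2 (-1.0 ± 0.11), each with adjusted p = 0.016. Nrn1 and Myot were also lower in sham RV than in sham LV, where 0 shared genes would be expected, while over all genes the 2 chamber differences correlated with r = 0.055 (rank correlation 0.064). Mstn, which encodes the growth inhibitor myostatin, stood at 0.80 ± 0.11 (adjusted p = 0.098). Nppa (0.47 ± 0.38), Nppb (-0.57 ± 0.42), Myh7 (-0.09 ± 0.42) and Acta1 (-0.81 ± 0.31) did not pass, nor did Myh6 (0.01 ± 0.07), Hand1 (-0.12 ± 0.11), Hand2 (-0.03 ± 0.09) or Tbx5 (0.27 ± 0.11). Of 58 extracellular matrix genes 0 passed by limma and 1 was higher adjusted over the list alone (median 0.52), with Thbs4 at 1.88 ± 0.80, Cilp at 1.60 ± 0.57 and Comp at 1.30 ± 0.40. In camera the list reached adjusted p = 4.3e-21, and adjusted p = 0.42 with an estimated correlation. Of 19 fibroblast markers 0 passed by limma and 5 were higher adjusted over the list alone (median 0.38), with Pi16 at 0.97 ± 0.21 (camera adjusted p = 1.8e-09, adjusted p = 0.37 with an estimated correlation). Of 23 endothelial markers 0 passed by limma and 3 were higher adjusted over the list alone (median 0.16), with Vwf at 1.17 ± 0.28 and Eng at 0.54 ± 0.15. Camera gave an adjusted p of 1.3e-06, and adjusted p = 0.31 with an estimated correlation. Respiratory chain genes were lower as a list in PAC (median -0.08, camera adjusted p = 2.3e-05, adjusted p = 0.73 with an estimated correlation). Of all genes 1470 had a moderated p below 0.05, not from an exact test. The gene count was 0 by limma without either TAC array, 12 without PAC 3 week array 1, 1 without array 2, 2 without either sham RV array, 0 in a fit to only the arrays compared (1940 at a moderated p below 0.05) and 0 without PAC 1 week array 2 and sham LV array 2 (1731), chosen after seeing the data. The respiratory chain median was -0.05 without PAC 3 week array 2.

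No gene passed the interaction of chamber and obstruction at 3 weeks in limma, so the gap between 1148 genes in PAC and 0 in TAC is not itself shown for any single gene. The interaction stood at 2.16 ± 0.54 for Nppa (adjusted p = 0.35), with Nppb at 1.43 ± 0.59 (adjusted p = 0.40), Myh7 at 1.04 ± 0.59 (adjusted p = 0.48) and Acta1 at 0.65 ± 0.44 (adjusted p = 0.55). Myh6 (0.00 ± 0.10), Hand1 (-0.18 ± 0.16), Hand2 (-0.37 ± 0.13, adjusted p = 0.37) and Tbx5 (0.15 ± 0.16) did not pass. The smallest p-values were those of Unc80 (-1.0 ± 0.15), an immunoglobulin kappa variable gene (-1.01 ± 0.16), Kctd12b (0.69 ± 0.11), Fuca2 (0.91 ± 0.16) and Mptx1 (-0.84 ± 0.16), each with adjusted p = 0.35. Camera called 11 of 30 lists at the preset correlation, of which 0 held with an estimated correlation and fry kept 1. A difference of lists between the chambers therefore rests on the preset correlation. Of 58 extracellular matrix genes 0 passed by limma and 0 adjusted over the list alone (median 0.72), with Postn at 2.07 ± 0.72, Col14a1 at 1.93 ± 0.54 and Cilp at 1.86 ± 0.81. For this list camera gave adjusted p = 5e-13, and adjusted p = 0.61 with an estimated correlation. Of 19 fibroblast markers 0 passed by limma and 5 were higher adjusted over the list alone (median 0.54), with Lum at 1.14 ± 0.29 (camera adjusted p = 8e-07, adjusted p = 0.61 with an estimated correlation). Endothelial markers (median 0.24, camera adjusted p = 5e-05) and glycolysis genes (median 0.15, camera adjusted p = 0.0027), with Slc2a1 at 0.80 ± 0.22 and Pfkl at 0.55 ± 0.13, went the same way, each with adjusted p = 0.61 with an estimated correlation. Load-responsive genes were not called (median 0.19, camera adjusted p = 0.065), nor cell cycle genes. Of all genes 2381 had a moderated p below 0.05, not from an exact test, and 3 genes passed without PAC 3 week array 1 and 2 in a fit to only the arrays compared. The fibroblast median was 0.33 without sham LV array 1.

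Across all genes the PAC and TAC changes at 3 weeks, which share no arrays, correlated with r = 0.372 (rank correlation 0.308, covariance 0.0151, 19938 genes). This agreement of PAC and TAC responses was 0.204 without sham LV array 2. Of the 642 genes higher in PAC 542 had a TAC change above 0 (median 0.11 against 0.55 in PAC), and of the 506 lower 354 had a TAC change below 0 (median -0.06 against -0.49). Over all comparisons 106 list tests were called with camera at the preset correlation and 1 with an estimated correlation, the Wnt pathway list between sham chambers.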

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

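Of the tests below, those of atrial tissue and the comparison of PAC RV with sham LV were fixed before the results were seen, and the loess tests, the cell cycle test without 1 array and the count of sham arrays at other times were chosen afterwards.

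The first pattern weighed is the gap between 1148 genes in PAC at 3 weeks and 0 in TAC, although no single gene passed the interaction. If a level-dependent distortion of the sham RV arrays had made it, loess scaling should have removed it, but 535 genes and an extracellular matrix median of 0.86 were left, which argues against distortion as the source of the matrix change. For the dim lymphocyte, nerve and lung lists, whose 38 genes had a median of -0.2, loess left -0.08 and called 0 of the 3 lists, as that explanation predicts. When PAC RV was compared with sham LV in place of sham RV, 0 genes passed by limma although 2182 had a moderated p below 0.05, not an exact one, and the matrix median was 0.79, so the number of genes may come from the sham RV arrays, with the caveat that chamber and sham differ together. The interaction called the matrix list but no gene, and the list call did not hold with an estimated correlation. Whether any such difference comes from load or from the chamber stays open.

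The rise of load genes together with atrial markers could reflect atrial muscle in the RV pieces. With the mean level of Myl7 and Sln as a covariate the mean of Acta1, Myh7 and Nppb over the PAC times stood at 1.89 ± 0.67 against 2.04 ± 0.37 without it. That mean cleared the bound set beforehand, but by a narrow margin given its larger standard error. With the covariate Nppa moved from 2.48 ± 0.31 to 1.39 ± 0.32 and the matrix median from 0.95 to 0.64. Genes past the threshold went from 4941 to 0 by limma, a loss whose cause was not tested. The covariate test therefore does not decide whether atrial tissue raised the load genes. Other atrial genes at 1 week, Kcnj3 (-0.17), Kcnj5 (-0.18), Pam (0.72) and Hey1 (0.18), had a median of 0.01 with a standard error of 0.07, which leaves the question open because sham RV already holds Kcnj3 at 8.95, Kcnj5 at 8.8, Pam at 11.59 and Hey1 at 7.26, above the median gene level of 6.74, so a small share of atrial tissue would be hidden and the bound set beforehand was wrong. The same genes differed by 0.21 with a standard error of 0.10 between sham LV array 2 and array 1, which leaves atrial tissue on that array open. Ventricular re-expression of Myl7, Myl4 and Bmp10 under load would look alike and was not tested.

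The cell cycle and macrophage lists were lower at 6 than at 1 week of PAC, with medians of -0.60 and -0.53, a difference found by testing the times against each other. A single array might have made these results. Without PAC 1 week array 2 the medians moved toward 0, to -0.33 for cell cycle and -0.29 for macrophage genes. What is left rests on 1 array at 1 week, so the test does not decide how much that array made. With an estimated correlation camera called neither list (adjusted p = 0.22 for cell cycle and 0.23 for macrophage genes). Recovery from the operation or age could also lower these genes, and with 0 sham RV arrays at 1 or 6 weeks that explanation is open. An early burst of proliferation in stromal and immune cells under load was not tested and stays open.

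Between 6 and 1 weeks of PAC 19 genes passed in a direct test of the difference between times, and 17 of them are named by the rule. Higher genes were Mmrn1 (3.70), Cpxm2 (1.69), Dct (1.33), Abra (1.20), Prune2 (0.85), Sncg (0.64) and Golga4 (0.62). Lower genes were Top2a (-1.82), Knl1 (-1.51), Ncapg (-1.51), Casq1 (-1.45), Mest (-1.44), Ccnb2 (-1.20), Ckap2 (-1.14), H2ac4 (-1.04), Epn3 (-0.95) and Pxdn (-0.85). Lists called in the same comparison were also complement and acute phase genes (median -0.21), smooth muscle and pericyte markers (0.13), atrial markers (-0.42), epicardial and mesothelial markers (-1.05) and circadian clock genes (0.13). With an estimated correlation these had adjusted p = 0.66, 0.22, 0.43, 0.22 and 0.23. The complement call ended without PAC 1 week array 2 (0.27) or PAC 6 week array 2 (0.12), the smooth muscle call without PAC 1 week array 1 (0.22) or PAC 6 week array 2 (0.12), and the atrial call without PAC 1 week array 2 (0.27). The clock call ended without PAC 1 week array 2 (0.11), either PAC 3 week array (0.052), PAC 6 week array 1 (0.12) or array 2 (0.051). Medians of lists still called also moved, to -0.97 for atrial genes without PAC 1 week array 1, and to -0.32 for complement and 0.20 for smooth muscle genes without PAC 6 week array 1.

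The interaction of chamber and obstruction is a direct test of a difference between chambers, and it called lists although no gene passed. The medians were 0.72 for extracellular matrix, 0.17 for TGF-beta and BMP, -0.17 for fatty acid oxidation, -0.06 for respiratory chain, 0.15 for glycolysis and 0.22 for macrophage genes. They were 0.35 for complement, 0.24 for endothelial, 0.54 for fibroblast, 1.34 for atrial and -0.22 for skeletal muscle genes. With an estimated correlation the adjusted p was 0.71 for fatty acid oxidation and macrophage genes, 0.77 for respiratory chain genes and 0.61 for the other lists. The fatty acid oxidation call ended without TAC array 1 (0.094) or sham RV array 1 (0.11). That of the respiratory chain ended without TAC array 1 (0.092), sham LV array 2 (0.11), PAC 3 week array 2 (0.14) or sham RV array 1 (0.29). Macrophage genes lost the call without TAC array 1 (0.094), sham LV array 1 (0.089), PAC 3 week array 2 (0.35) or sham RV array 1 (0.068), and complement genes without TAC array 1 (0.086), sham LV array 1 (0.14) or PAC 3 week array 2 (0.22). Loess scaling ended the macrophage and skeletal muscle calls (0.057 each), and leaving out genes below the median level those of the TGF-beta and BMP (0.061), macrophage (0.18) and complement lists (0.085). Medians of lists still called also moved. They were 0.28 for atrial and 0.09 for TGF-beta and BMP genes without PAC 3 week array 2, 0.11 for TGF-beta and BMP and -0.12 for respiratory chain genes without sham RV array 2, and 0.39 for macrophage genes without PAC 3 week array 1. They were 0.89 for atrial genes without sham LV array 2, 0.33 for fibroblast and -0.14 for skeletal muscle genes without sham LV array 1, and -0.26 for fatty acid oxidation genes without TAC array 2.

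Of 1621 probe sets with several genes 77 passed in PAC at 3 weeks, 39 higher and 38 lower, and these stand out because they carry no single gene. Of 12146 unlisted probe sets 0 passed at 3 weeks by limma and 208 passed over the mean of the PAC times, 134 higher and 74 lower.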

How the results depend on the processing

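The alternatives here were fixed beforehand, apart from the joint removal of PAC 1 week array 2 and sham LV array 2, which was chosen after the results were seen; the cause of changes in the counts was not tested. None of the named genes or lists that passed changed the sign of its test under any alternative, though the median of the immediate early list at 1 week was -0.01 without PAC 1 week array 2, alone or with the joint removal; most counts rest on few arrays and 1 of 106 list calls was kept with an estimated correlation. With each array left out in turn the counts ran from 227 to 4557 for PAC at 1 week, 3 to 2070 at 3 weeks, 3 to 2656 at 6 weeks, 296 to 6235 for the mean, 1 to 488 for 6 against 1 week, 0 to 1 for TAC, 0 to 252 for sham RV against LV, 0 to 12 for PAC against TAC and 0 to 3 for the interaction. The list calls ran from 92 to 126 and the correlation of PAC with TAC from 0.204 to 0.416. Of the calls of named genes 1208 ended when an array was left out and 2488 were kept.

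Loess scaling gave 2174, 535, 1279 and 3045 genes for PAC at 1, 3 and 6 weeks and their mean, 21 for 6 against 1 week, 82 for the sham chambers, and 87 list calls. Leaving out genes below the median level gave 2694, 1587, 2437, 3685, 32 and 871 genes, 77 list calls and 0.457 for the agreement of PAC and TAC responses; it left too few lymphocyte, nerve and lung genes to test and gives no value for named genes below that level. The trended and robust prior gave 3817, 1648, 2337, 5162, 83 and 723 genes, and 5 for PAC against TAC. Fitting only the arrays compared gave 89, 1090, 1020, 2914, 1 and 6 genes, 0 for PAC against TAC and 2 for the interaction. The mean over probe sets gave 3630, 1145, 1843, 4917, 19 and 80. The joint removal of 2 arrays gave 167, 1545, 2043, 3502, 5 and 0 genes, 0 for PAC against TAC by limma and 121 list calls. Fry called 47 lists. Of the lists called by camera it kept 5 of 15 in PAC at 1 week, 8 of 17 at 3 weeks and 7 of 19 at 6 weeks. Between 6 and 1 weeks it kept 0 of 7.

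Pairing of arrays by replicate number as a block gave 3761, 1387, 1941, 5046, 11 and 56 genes and 113 list calls, and ended no list call. It ended 8 of 17 calls of named genes between 6 and 1 weeks of PAC and 5 of 20 between the sham chambers, whose pieces may share hearts. Differences between replicates 1 and 2 correlated at 0.26, 0.37 and 0.26 between the 3 PAC groups and at -0.24 to 0.11 between the other groups, so a batch shared by PAC arrays of the same number is left open.

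Values that changed sign were all of genes that did not pass. With loess Myh6 at 1 week was 0.02, Hand1 at 6 weeks 0.01 and the Myh6 interaction 0.03. With the 2 arrays removed Nppa, Acta1 and Per1 between 6 and 1 weeks were 0.46, 0.07 and 0.03, and Hand2 in TAC 0.00. With each array left out the ranges were, for PAC at 1 week, -0.17 to 0.07 for Tbx5, and at 6 weeks -0.14 to 0.01 for Hand1. Between 6 and 1 weeks they were -0.47 to 0.46 for Nppa, -0.11 to 1.35 for Nppb, -0.55 to 0.07 for Acta1 and -0.67 to 0.03 for Per1. For TAC they were -0.15 to 0.80 for Nppa, -0.27 to 0.03 for Hand1 and -0.03 to 0.13 for Hand2. Between sham chambers they were 0.00 to 0.03 for Myh6, -0.01 to 0.13 for Hand1 and -1.58 to 0.33 for Sfrp2. For PAC against TAC they were 0.00 to 0.03 for Myh6, -0.46 to 0.28 for Myh7, -0.27 to 0.03 for Hand1, -0.11 to 0.05 for Hand2 and -0.02 to 4.24 for Bmp10. For the interaction of Myh6 the range was -0.02 to 0.02, and for Nr4a1 over the mean -0.23 to 1.32.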

Other observations

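The test of chamber genes below was chosen after the result was seen, and the lists were fixed before.

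Clock genes at 6 weeks of PAC differed from the 3 week sham arrays. At 6 weeks of PAC 6 of 17 circadian genes rose and 3 fell (7 and 4 adjusted over the list alone, median 0.23), with Bhlhe40 at 1.53 ± 0.25 (adjusted p = 0.012), the output gene Dbp at 1.43 ± 0.16 (adjusted p = 0.0051), Nr1d1 at 0.99 ± 0.14 and Nfil3 at -0.93 ± 0.13. At the preset correlation camera gave adjusted p = 0.011, with adjusted p = 0.37 with an estimated correlation, 0.080 with loess scaling and 0.68 without genes below the median level. At 1 week 5 rose and 3 fell (median 0.13, camera adjusted p = 0.13), and at 3 weeks 0 passed by limma (median -0.02, camera adjusted p = 0.79). Dbp was 9.17 and 9.48 on the 1 week arrays, 9.28 and 9.63 on the 6 week arrays and 7.85 to 8.28 on all other arrays. Between 6 and 1 weeks 0 clock genes passed by limma, and without sham arrays at those weeks time of sampling and obstruction were not separated.

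Among lists of other cells, lymphocyte markers were lower at 1 week of PAC, with 5 of 17 lower and 0 higher (7 adjusted over the list alone, median -0.24). Nkg7 fell by -0.69 ± 0.11, Cd8a by -0.45 ± 0.12 and Cd3e by -0.44 ± 0.10 (camera adjusted p = 0.0058, adjusted p = 0.39 with an estimated correlation). At 3 weeks the list had a median of -0.19 (camera adjusted p = 0.018, 0.14 without sham RV array 2, adjusted p = 0.40 with an estimated correlation). Nerve (median -0.23, camera adjusted p = 0.025) and lung lists (median -0.22, camera adjusted p = 0.026) were lower at 3 weeks too, each with adjusted p = 0.40 with an estimated correlation. The nerve call ended without PAC 3 week array 2 (0.058) or sham RV array 1 (0.098), and the lung call without PAC 3 week array 2 (0.050) or sham RV array 2 (0.086). Loess scaling ended the lymphocyte call at 1 week (adjusted p = 0.28) and 3 weeks (0.53), and the nerve (0.16), lung (0.19) and skeletal muscle calls (0.081 at 1 week, and 0.065 without genes below the median level). The median level of the lymphocyte list was 5.62 and of the lung list 4.97, under the medians of unlisted probe sets (5.65 to 5.79). Over all genes in deciles 3 and 4 of level the median change was -0.22 at 1 week and -0.18 at 3 weeks. The lower lists are therefore not read as a loss of these cells. Skeletal muscle markers had 4 of 18 lower and 1 higher at 1 week (9 and 1 adjusted over the list alone, median -0.28), with Casq1 up by 1.69 ± 0.22 and Myog (-0.62 ± 0.15), Tnni2 (-0.59 ± 0.11) and Atp2a1 (-0.50 ± 0.12) down. As a list they had camera adjusted p = 0.0052, and adjusted p = 0.39 with an estimated correlation. At 6 weeks conduction system markers had 1 of 13 higher and 3 lower (2 and 6 adjusted over the list alone, median -0.32), with Gjc1 at 0.54 ± 0.14, Isl1 at -0.49 ± 0.13, Etv1 at -0.42 ± 0.10 and Hcn4 at -0.40 ± 0.09. Tested with camera the list had adjusted p = 0.034, with adjusted p = 0.37 with an estimated correlation, 0.053 without PAC 6 week array 2, 0.10 without sham RV array 1, 0.061 with loess scaling and 0.58 without genes below the median level. Calcium handling and ion channel genes had 1 of 31 higher and 2 lower at 6 weeks (median -0.16), with Kcnj3 at -0.63 ± 0.12 and Asph at 0.31 ± 0.08 (camera adjusted p = 0.028, adjusted p = 0.51 with an estimated correlation, 0.071 without PAC 6 week array 2 and 0.10 without sham RV array 1). Complement genes were called between PAC and TAC (median 0.27, camera adjusted p = 0.0023, 0.40 without PAC 3 week array 2), as were cytokine and chemokine genes (median 0.13, camera adjusted p = 0.0079, 0.31 without TAC array 1 and 0.38 without PAC 3 week array 2). With an estimated correlation these were adjusted p = 0.46 and adjusted p = 0.61. The lymphocyte median at 3 weeks was -0.30 without sham RV array 1, and the cytokine median was 0.20 without TAC array 2 and 0.21 without PAC 3 week array 1.

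Of 66 Wnt pathway genes 5 rose and 11 fell at 1 week of PAC, but camera did not call the list there (median -0.18, adjusted p = 0.066) or at 3 weeks (-0.15, adjusted p = 0.052). Fry called it lower at 1, 3 and 6 weeks and over their mean (adjusted p = 0.00039, 0.00095, 0.0054 and 0.00039). At 3 weeks of PAC lists without a camera call were adipocyte markers (0 of 12 higher and 2 lower, adjusted p = 0.11), patterning transcription factors (median -0.13, adjusted p = 0.13) and unfolded protein response genes (-0.01, adjusted p = 0.61). Splicing regulators (0.05, adjusted p = 0.22) and natriuretic, renin-angiotensin and endothelin genes (0.03, with 3 of 21 higher and 2 lower, adjusted p = 0.58) were not called either. Camera called these 5 lists in none of the comparisons. Fry called the patterning list as lower in PAC at 1, 3 and 6 weeks and their mean (adjusted p = 0.0037, 0.0023, 0.0050 and 0.0012) and as higher in sham RV than sham LV (0.0025), and called none of the other 4. All of these patterning calls share the sham RV arrays.

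The genes that differ between sham chambers may mark a lasting chamber difference. Of the 82 genes, 79.3% (65 genes) kept their direction between the obstructed ventricles, as that explanation predicts. The share came from genes lower in RV, of which 59 of 67 kept the direction (median -0.62 in sham and -0.16 under obstruction), while 6 of 15 genes higher in RV did so (0.69 and -0.04). Nrn1 and Myot, lower in RV in both settings, are candidates for chamber genes that obstruction leaves in place. Wif1 was at 7.77 and 7.44 in sham RV, 6.68 to 7.13 in PAC RV and 6.25 to 6.64 in LV. The same sham RV arrays served to pick Wif1 and as the only baseline for a fall under load. A deviation of those arrays alone could give both, so these values do not decide whether load lowers Wif1. In situ staining of Wif1, Nrn1 and Myot in both chambers of sham and obstructed hearts, with more sham animals, would test these differences.

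Some questions stay open. Whether the load was larger after PAC than after TAC was not tested here, and graded PAC and TAC with Postn, Cilp and Nppa measured against pressure in each heart would show it. Which cells divide at 1 week was not tested either, and labelling of dividing cells with sham hearts at 1 and 6 weeks would answer it.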
